A study of Homo sapiens with 3 samples.

How the data were processed

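Expression was measured by RNA sequencing of total RNA from SZ95 sebocytes, with 3 libraries of 1 sample per group. The authors deposited a gene table whose columns hold FPKM values, 1 column per sample, per the file headers. The submitters' processing notes name HISAT2, StringTie, DESeq2 and the genome build GRCh38, without versions, roles or order; the annotation release, filters and any scaling between samples are not given in the sources used here. Each column was assigned to its group by its name, which matches the sample label. Coordinates are those of the deposited table.

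Gene types, transcript GC content (over all annotated transcripts of a gene) and median transcript length were taken from GENCODE release 29, which held 57836 of the 58174 gene identifiers, 56033 of them with the same start and end. The FPKM sums were 671353, 545370 and 601029 in the LA, LA with P. acnes and LA with PGN libraries. Depth was estimated from genes with 1 annotated transcript of more than 400 bases. The most frequent low product of FPKM and length was taken as 1 fragment. By that estimate 1 fragment per kilobase was worth 0.068, 0.10 and 0.070 FPKM, or about 14700000, 9820000 and 14300000 fragments. Within 1% of that product lay 571, 197 and 733 of 6726, 3398 and 9690 such genes above 0. The 1% is a search window, and the accuracy of the estimate is not known. Fragment numbers given for single genes rest on this estimate and the median transcript length, and no counts were recovered, so no count test or counting interval was used.

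Log2 ratios were computed as log2 of FPKM + 1 in both libraries, which understates the difference of low genes. A gene was kept in a comparison when the higher of its values was at least 1 FPKM, and a 2-fold ratio was the rule of size. With 1 library per group no test was possible and no p-value was computed. The genes named were, per comparison, the 8 highest and 8 lowest log2 ratios among protein-coding genes whose higher value was at least 5 FPKM, the genes CYP1A1, CYP1B1, AHRR, TIPARP, NQO1 and AHR whatever their value, and up to 4 kept members of a list with the largest absolute log2 ratio. This rule and 35 gene lists were fixed before the data were examined. EEF1G, AL365205.1, NME1, NME2, CBS, KRT18, ASNS with PGN, the non-coding RNAs and the genes of opposite direction in the closing section were chosen after their values were seen. A list with at least 3 kept members was described by the percentile of its median among 10000 random lists of the same size drawn from 10 expression classes. The interval of the ribosomal protein median in the closing section comes from 10000 resamplings of its genes. Some genes that this rule selects are not reported here. Genes at 0 in a library are given as listed at 0, without a ratio.

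For the shared LA library, 100 sets of libraries without differences were drawn as Poisson fragments from the LA values at the estimated depths. Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter, a minimum of 5 FPKM, centring on the median of genes at 10 FPKM or more in both libraries, protein-coding genes alone, upper-quartile scaling and rules of 1.5-fold and 4-fold. Alternatives added after the data were seen were a GC adjustment (subtracting the median of genes in the same of 20 GC classes within 3 expression classes), random lists matched on 6 expression and 10 GC classes, and removal of the mitochondrially encoded genes with rescaling.

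The scripts were tested on simulated data with 200 genes of known difference. For LA with P. acnes over LA (12346 genes), 100% of 4-fold and 41% of 2-fold genes passed the rule, with 1.61% of the other genes. For LA with PGN over LA (12222 genes) these shares were 100%, 37% and 1.06%, and for LA with PGN over LA with P. acnes (12284 genes) 100%, 24% and 1.65%. The simulated libraries were drawn from the LA values with Poisson counting noise alone. Differences between cultures or preparations were left out, so the shares of other genes are not error rates for the real libraries. With a simulated GC trend in LA with P. acnes over LA (12564 genes), 18.8% of the other genes passed without and 1.06% with the GC adjustment. Of the 2-fold genes, 48% passed without and 30% with it. The simulated trend was gentler than that of the P. acnes library and the same at every expression level. It therefore does not test the adjustment on a trend like the real one. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.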

Results

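Total RNA of SZ95 cells, an immortalised human sebaceous gland line used as a model of sebocytes, was sequenced in 3 groups. The labels name them LA, LA with P. acnes (a skin bacterium of the pilosebaceous unit) and LA with PGN (peptidoglycan, a bacterial cell wall polymer). LA is not spelled out in the labels, and each group has 1 library. The study set out to ask whether the bacterium and its cell wall polymer act on the aryl hydrocarbon receptor (AhR), a ligand-activated transcription factor, and on sebocyte differentiation. The table of FPKM values (fragments per kilobase of transcript, scaled to the size of the library) lists 58174 genes, of which 26073, 18004 and 32224 were above 0 in the LA, LA with P. acnes and LA with PGN libraries. Estimated from the most frequent low values, depth was about 14700000, 9820000 and 14300000 fragments. There are no replicates, so no difference below has a replicate check and none was tested. Each describes these libraries rather than the conditions.

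The comparison of LA with P. acnes against LA addresses the response to the bacterium. Transcripts of the actin-bundling protein fascin (FSCN1, chromosome 7, 5592823 to 5606655, GRCh38) stood at 113.6 FPKM against 2.02 in LA, a log2 ratio of 5.25. IRAK1, a kinase downstream of Toll-like receptors (chromosome X, 154010500 to 154019980), was at 192.4 against 6.91 FPKM (log2 ratio 4.61). SYNGR2 was at 251.4 against 10.05 FPKM, and LAD1, a protein of basement membrane anchoring filaments, at 205.1 against 10.1 FPKM. With PGN, FSCN1, IRAK1, SYNGR2 and LAD1 were above LA too, at 42.2, 32.1, 134.9 and 136.4 FPKM. At the other end, transcripts of ribosomal proteins and of mitochondrial respiration were far lower. RPL36A was at 3.72 against 2347 FPKM (log2 ratio -8.96), RPL39 at 2.46 against 1420 FPKM (-8.68), RPL7 at 2.44 against 1304 FPKM (-8.57) and RPS27A at 11.9 against 3132 FPKM (-7.92). MT-ND6, a mitochondrially encoded subunit of respiratory complex I, was at 5.73 against 2746 FPKM (-8.67), and ATP5H, a nuclear-encoded subunit of ATP synthase, at 0.69 against 378.4 FPKM (-7.81). With the median of genes of like GC content and expression subtracted, these log2 ratios were smaller: 3.81 for FSCN1, 3.18 for IRAK1, -4.57 for RPL36A, -4.56 for RPL39, -4.17 for RPL7, -3.80 for RPS27A, -4.15 for MT-ND6 and -3.69 for ATP5H.

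Of 12535 genes kept (1 FPKM or more in either library), 2341 were at least 2-fold higher and 5629 at least 2-fold lower with P. acnes, so 29.4% of these genes were higher. The log2 ratios followed the GC content of the transcripts. Over 5532 protein-coding genes with a mean of at least 5 FPKM, Spearman's rho between GC content and log2 ratio was 0.76 across genes, which are not independent replicates. The median log2 ratio went from -3.57 in the lowest of 10 equal groups of genes by GC content to 1.52 in the highest. After this GC subtraction, an alternative chosen after the data were seen, 2079 genes were higher and 1955 lower (51.5% higher), and 716 and 1610 of them were also called without it. Centring on genes at 10 FPKM or more in both libraries subtracts 0.72 from every log2 ratio, which moves the median of kept genes from -0.77 to -1.50 and the share of higher genes to 8.0%. Only 2664 genes set that centre, and genes that are low with P. acnes are left out of it. Centring is therefore not a neutral check here, and how far it reflects the GC trend was not tested.

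**Figure D1:**
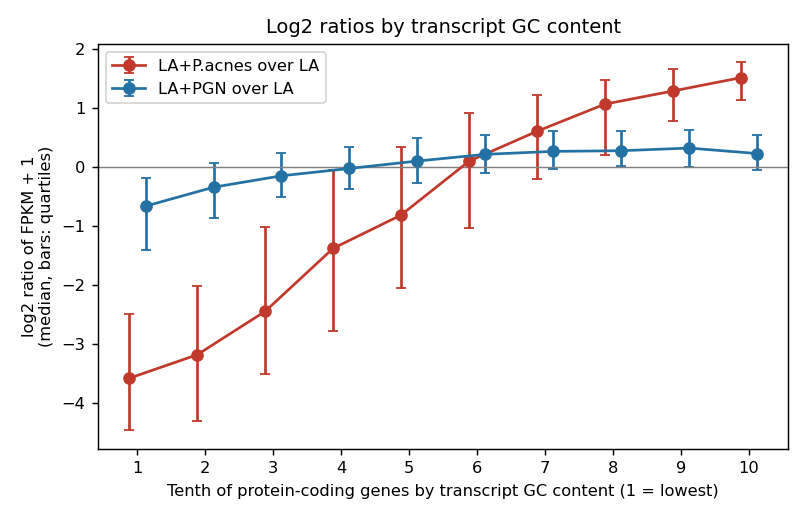
Median log2 ratio of FPKM + 1 (vertical axis, bars span the quartiles) for 10 equal groups of protein-coding genes ordered by transcript GC content (horizontal axis), for LA with P. acnes over LA (circles, red) and LA with PGN over LA (circles, blue). The P. acnes medians go from -3.57 to 1.52 and the PGN medians from -0.66 in the lowest group to 0.24 in the highest.

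With P. acnes, AhR targets lay on both sides of LA. CYP1A1, the classical AhR-induced monooxygenase (chromosome 15, 74719542 to 74725610), was listed at 0 with P. acnes and at 0.36 FPKM in LA. CYP1B1, a related enzyme, was at 0.40 against 0.26 FPKM and TIPARP, an AhR-induced ADP-ribosyltransferase, at 0.058 against 0.33 FPKM. AHRR, the AhR repressor, was at 5.18 against 1.90 FPKM (log2 ratio 1.09, and 0.57 once genes of like GC content were subtracted, short of the 2-fold rule), and lies in a locus that overlaps PDCD6 on the same strand. NQO1, a quinone reductase, was at 13.2 against 95.1 FPKM (log2 ratio -2.76), but its ratio was positive (1.36) once genes of like GC content were subtracted. SLC7A5, an amino acid transporter, was at 337.4 against 81.1 FPKM (2.04). The receptor itself, AHR, was at 0.060 against 0.16 FPKM. Of 7 kept members of the AhR target list, 2 were at least 2-fold higher and 2 lower (1 and 2 after centring). The list's median log2 ratio of 0.05 was at percentile 74.6 of random lists matched on expression. After the GC subtraction 4 were higher, not counting AHRR, and 0 lower, with a median of 1.12. In the receptor complex list, 1 of 7 kept members was higher and 3 were lower, among them the chaperones HSP90AA1 (0.95 against 39.1 FPKM) and HSP90AB1 (13.9 against 251.8 FPKM); after the GC subtraction 1 was higher and 0 were lower, and HSP90AA1's ratio was 0.030. At the depth found here and the median length of its annotated transcripts, the CYP1A1 value in LA is worth about 9.9 fragments, so a modest difference in this gene cannot be read from these libraries.

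**Figure D2:**
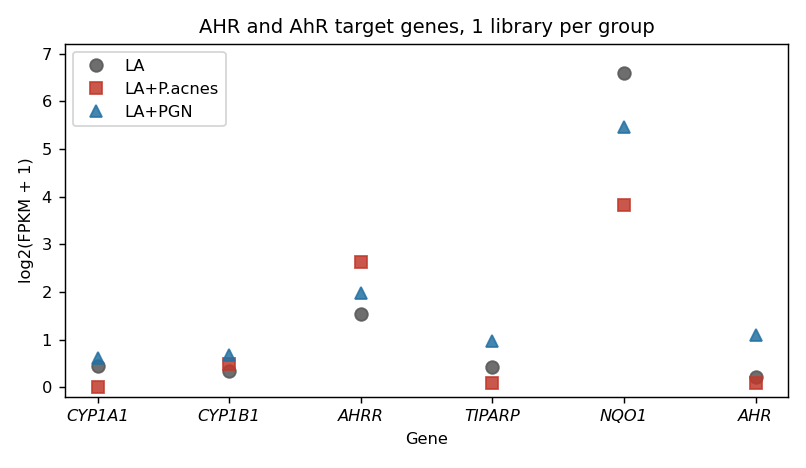
Level of AHR and of the AhR targets CYP1A1, CYP1B1, AHRR, TIPARP and NQO1 as log2(FPKM + 1) on the vertical axis, with 1 point per library (circles LA, squares LA with P. acnes, triangles LA with PGN). NQO1 is highest in LA at 95.1 FPKM and lowest with P. acnes at 13.2 FPKM, and the highest value of the other genes is 5.18 FPKM, for AHRR with P. acnes.

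In 4 lists of lipid genes more genes were at least 2-fold lower than higher with P. acnes. The same held for all 10162 kept coding genes, of which 4499 were lower and 1863 higher. Of 15 kept genes of fatty acid synthesis and desaturation, 8 were at least 2-fold lower and 2 higher; SCD, the stearoyl-CoA desaturase, was at 0.74 against 17.0 FPKM (-3.38) and FADS1 at 1.78 against 16.5 FPKM (-2.65). Of 21 cholesterol genes, 11 were lower and 2 higher, with FDPS at 11.8 against 224.4 FPKM (-4.14) and MSMO1 at 0.20 against 18.3 FPKM (-4.01). Among 14 genes of triglycerides, wax esters and lipid droplets 6 were lower and 3 higher, and PLIN2, a lipid droplet coat protein, was at 0.89 against 9.38 FPKM (-2.46). In the list of PPAR targets and fatty acid oxidation 11 of 19 were lower and 3 higher, and PPARG, a receptor that drives sebocyte maturation, was listed at 0 against 7.70 FPKM in LA. None of these 4 lists had a median outside the central 95% of random lists of like expression, their percentiles being 24.2, 18.2, 38.1 and 2.82. Their GC-adjusted medians were -0.11, -0.05, 0.13 and -0.17, with 2, 2, 0 and 2 genes higher and 5, 4, 1 and 1 lower. Of 10 kept sebaceous lineage markers 3 were higher and 2 lower (1 and 2 after centring), with a median of 0.57 at percentile 83.4. After the GC subtraction 2 of these markers were higher and 0 lower, with a median of 0.022. Among them, keratins of simple epithelium differed: KRT8 was at 10388 against 2766 FPKM (1.91) and KRT7 at 3164 against 1082 FPKM (1.55), while KRT18, the partner of KRT8, was at 2623 against 2504 FPKM (0.067).

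At the scaling of the table, innate immune genes went both ways. In the list of pattern recognition receptors and adaptors, 4 of 11 kept genes were higher and 6 lower; besides IRAK1, the lipopolysaccharide co-receptor CD14 was at 8.92 against 2.53 FPKM (1.49), while the inflammatory caspase CASP1 was listed at 0 against 7.41 FPKM. Of 16 NF-kB feedback targets 5 were higher and 4 lower, with TNFAIP2 at 25.8 against 1.78 FPKM (3.26), NFKB2 at 77.6 against 25.1 FPKM (1.59) and the adhesion molecule ICAM1 at 2.31 against 19.5 FPKM (-2.63). No kept cytokine or chemokine was at least 2-fold higher and 4 of 11 were lower, including the interleukin 1 receptor antagonist IL1RN at 2.08 against 21.3 FPKM (-2.86) and CXCL1 at 2.09 against 12.8 FPKM (-2.15). Of 8 antimicrobial peptide genes 5 were lower, with SLPI, a secreted protease inhibitor, at 25.3 against 2880 FPKM (-6.77). The percentiles of these 4 lists were 30.1, 92.3, 73.8 and 5.15. After centring, 1, 1, 0 and 0 of their genes were higher and 7, 6, 5 and 5 lower. After the GC subtraction 2, 2, 4 and 1 of their genes were higher and 0, 2, 0 and 3 lower, so the counts of the cytokine list were turned round. As a whole the cytokine list then had a median of -0.030, and it was at percentile 84.1 with GC matching. Interferon-stimulated genes were lower in 10 of 17 and higher in 3, among which ISG15 was at 1523 against 406.7 FPKM (1.90); after the GC subtraction 2 were lower and 1 was higher.

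Stress and growth genes contained the lists that stood apart from random lists. Of 33 lists, 4 lay outside the central 95%, and 2 with GC matching. With so many lists, some can lie outside it by chance. The heat shock list (7 of 11 lower, median -2.05) was at percentile 1.99, with HSPA8 at 5.004 against 461.4 FPKM (-6.27) and HSPD1 at 1.65 against 118.2 FPKM (-5.49). The p53 target list (5 of 10 higher, median 1.01, but -0.19 with no filter on low values) was at percentile 98.0, with PHLDA3 at 121.1 against 18.0 FPKM (2.68) and CDKN1A, the cell cycle inhibitor p21, at 24.5 against 110.3 FPKM (-2.13). Centring, which subtracts 0.72 from every log2 ratio, leaves fewer p53 targets higher and does not change the percentile. All 13 mitochondrially encoded mRNAs (median -6.71) and 19 of 30 listed cytosolic ribosomal protein genes (median -2.12) were lower, both at percentile 0. Against random lists matched on GC content as well, these percentiles were 13.98, 84.8, 0.08 and 52.4 in turn, so the mitochondrial list alone of these 4 stayed outside the central 95%. After the GC subtraction 1, 1, 0 and 4 of their genes were higher and 4, 1, 13 and 13 lower. The histone list (3 of 7 higher, median 0.86) was at percentile 97.46, and at 98.5 with GC matching (5 higher after the GC subtraction). The count of 3 and the median are those without centring, which subtracts 0.72 from each log2 ratio. Cell cycle genes were lower in 16 of 27 and higher in 5 (percentile 3.61), with CCNB1 at 1.06 against 68.4 FPKM (-5.07), and at percentile 55.3 with GC matching; after the GC subtraction 6 were lower and 7 higher, and the excess of lower genes was gone. Over 4 lists of markers of other cell types, 2 genes were at 10 FPKM or more and at least 2-fold above LA, the macrophage-associated CD68 at 44.6 against 2.59 FPKM (3.67) and FBLN1 at 245.0 against 107.1 FPKM (1.19).

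**Figure D3:**
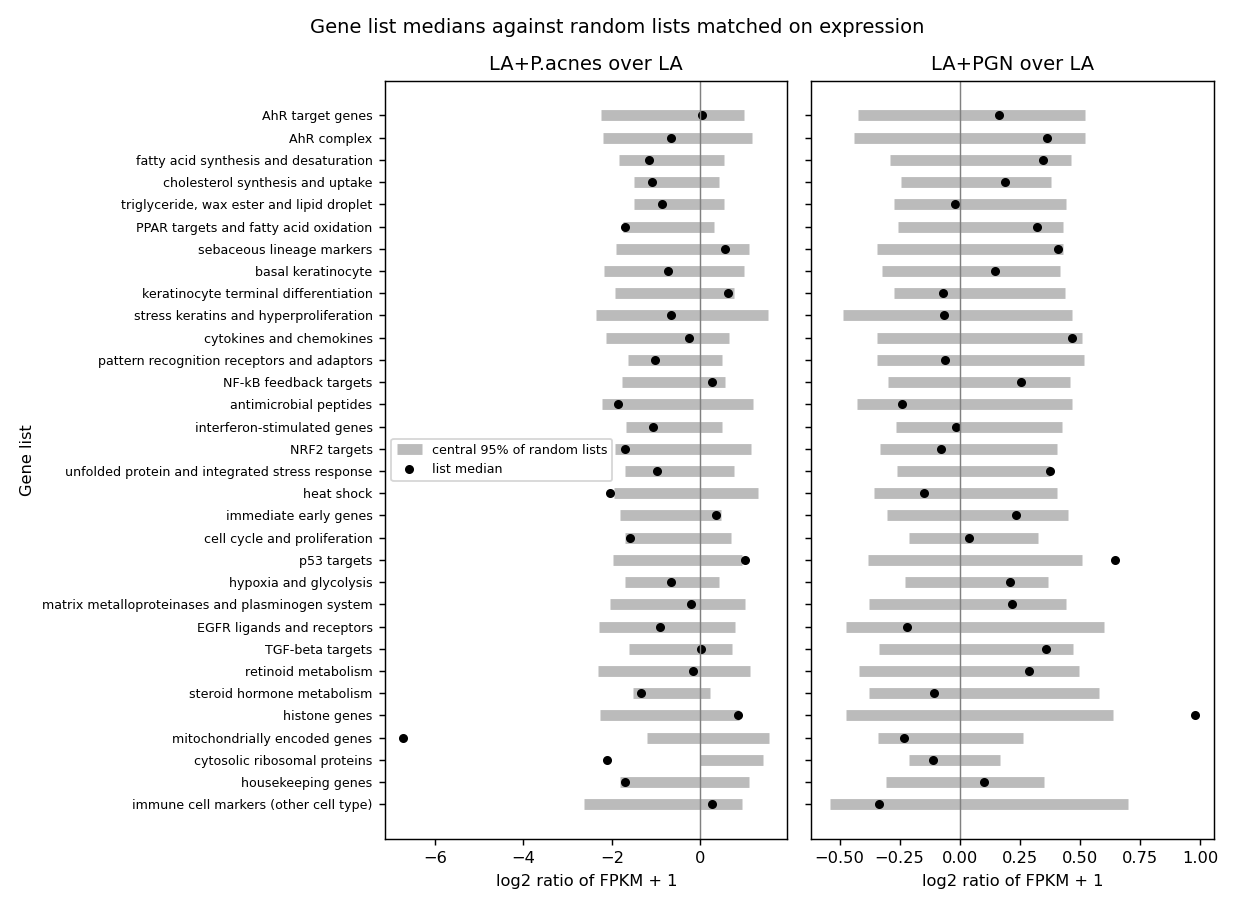
Median log2 ratio of FPKM + 1 (points, horizontal axis) of each gene list (vertical axis) for LA with P. acnes over LA (left panel) and LA with PGN over LA (right panel), whose horizontal scales differ. Grey bars span the central 95% of 10000 random lists matched on expression; the mitochondrially encoded mRNAs lie at -6.71 on the left and -0.23 on the right.

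The comparison of LA with PGN against LA addresses the response to the polymer, and these libraries were more alike (Pearson's r of log2(FPKM + 1) across genes 0.92, against 0.67 for P. acnes and LA). OGFR, a receptor for an opioid growth factor (chromosome 20, 62804835 to 62814000), was at 81.7 against 4.32 FPKM (log2 ratio 3.96). FSCN1 was at 42.2 against 2.02 FPKM (3.84), RNPEPL1 at 45.3 against 2.25 FPKM (3.83), CYB561 at 22.3 against 0.55 FPKM (3.91) and RETREG3 at 21.5 against 0.69 FPKM (3.74). CLDN4, a tight junction protein (chromosome 7, 73799542 to 73832693), was at 3.72 against 165.5 FPKM (-5.14), while with P. acnes it was at 221.5 FPKM. FKBP1A, the binding protein of the drug FK506, was at 26.6 against 625.3 FPKM (-4.50), CEBPZ at 1.25 against 44.0 FPKM (-4.32), OSER1 at 2.28 against 48.6 FPKM (-3.92) and C8orf59 at 3.25 against 63.1 FPKM (-3.92). The ratios of CEBPZ and C8orf59 were -3.36 and -2.95 after the GC subtraction. FKBP1A, CEBPZ, OSER1 and C8orf59 were below LA with P. acnes too, at 14.4, 0.088, 0.68 and 0.70 FPKM. OGFR, RNPEPL1, CYB561 and RETREG3 were above LA there, at 36.0, 30.7, 3.50 and 1.07 FPKM. Such ratios may rest on the LA value that both comparisons share. Of 12989 kept genes 1093 were at least 2-fold higher and 1077 lower (50.4% higher). Scaling by the upper quartile of genes above 0, which moves the median log2 ratio from 0.08 to 0.64, gave 3588 higher and 502 lower (87.7% higher). That quartile was taken over 26073 genes in LA and 32224 with PGN, while 11646 and 12048 genes were at 1 FPKM or more. Centring on the 4123 genes at 10 FPKM or more in both libraries subtracts only 0.048 from each log2 ratio. It gave 979 higher and 1170 lower (45.6% higher). Spearman's rho between GC content and log2 ratio across genes was 0.41.

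With PGN, CYP1A1 was at 0.53 against 0.36 FPKM, values worth about 13.9 and 9.9 fragments. CYP1B1 was at 0.60 against 0.26 FPKM, TIPARP at 0.97 against 0.33 FPKM, AHRR at 2.91 against 1.90 FPKM and AHR at 1.13 against 0.16 FPKM. All 5 lay above LA by less than the 2-fold rule on the log2(FPKM + 1) scale, the largest log2 ratio being 0.88 for AHR. NQO1 was at 43.1 against 95.1 FPKM (-1.12), and short of the 2-fold rule after the GC subtraction (-0.68). SLC7A5 was at 209.9 against 81.1 FPKM (1.36) and SERPINB2 at 1.95 against 0.35 FPKM (1.13). The AhR target list had 2 of 8 kept members higher and 1 lower (percentile 62.5), and the receptor complex list 1 of 8 higher, SRC at 23.3 against 9.87 FPKM (1.16). The target list had 2 higher and 0 lower after the GC subtraction, and the complex list 0 of either. With upper-quartile scaling 3 of 10 targets and 4 of 8 members of the complex list were higher and 0 lower.

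Cholesterol genes included 4 of 21 that were higher with PGN, among them LSS, the lanosterol synthase, at 16.5 against 2.28 FPKM (2.41) and the regulator SREBF2 at 31.6 against 9.12 FPKM (1.69); 1 was lower (0 after the GC subtraction) and the list was at percentile 73.6. At the scaling of the table no fatty acid synthesis gene of 15 passed the 2-fold rule in either direction, and none of 12 sebaceous lineage markers did (1 was lower after the GC subtraction); these lists were at percentiles 90.5 and 96.9. With upper-quartile scaling 6 of the fatty acid synthesis genes, 8 of the sebaceous markers and 7 of the cholesterol genes were higher and 0 lower.

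Upper-quartile scaling moves the median log2 ratio of all kept genes with PGN from 0.08 to 0.64, and centring moves it to 0.036. Counts of immune genes therefore depend on which scaling is used. At the scaling of the table, of 13 kept cytokines and chemokines 2 were higher and 2 lower with PGN, of 12 pattern recognition receptors and adaptors 1 and 1, of 15 NF-kB feedback targets 3 and 0, and of 8 antimicrobial peptide genes 0 and 0. These lists were at percentiles 96.1, 22.0, 79.5 and 10.9, and after the GC subtraction 2, 1, 2 and 0 of their genes were higher and 2, 0, 0 and 0 lower. Among them, TNIP1, an inhibitor of NF-kB signalling, was at 223.5 against 63.0 FPKM (1.81), IRAK1 at 32.1 against 6.91 FPKM (2.07), IL1B at 3.36 against 0.65 FPKM (1.40), IL23A at 6.12 against 2.18 FPKM (1.16), CCL5 at 13.4 against 28.7 FPKM (-1.04) and IL1RN at 3.88 against 21.3 FPKM (-2.19), while LY96 was listed at 0 against 1.56 FPKM in LA. The p53 target list had a median of 0.65 at percentile 99.6 with 1 of 11 members past the 2-fold rule, PLK3 at 33.2 against 10.4 FPKM (1.59). The histone list had a median of 0.98 at percentile 99.8, with 3 of 7 higher and HIST1H4H at 13.6 against 1.53 FPKM (2.53). Matched on GC content as well, these lists were at percentiles 99.5 and 99.8. Of 32 lists, 3 lay outside the central 95% of random lists, and 2 with GC matching. With so many lists, some can lie outside it by chance. The unfolded protein and integrated stress response list had 2 of 19 higher and 3 lower (1 and 2 after the GC subtraction), with a median of 0.37 at percentile 97.54 (96.8 with GC matching). It held the endoplasmic reticulum chaperones HSPA5 at 27.4 against 114.04 FPKM (-2.02) and HSP90B1 at 121.2 against 494.2 FPKM (-2.02) and the asparagine synthetase ASNS at 27.0 against 55.1 FPKM (-1.004) on the low side, and CHAC1 at 17.0 against 5.73 FPKM (1.42) and DDIT3 at 20.4 against 7.72 FPKM (1.30) on the high side. With upper-quartile scaling 6 of 11 p53 targets, 7 of 7 histone genes and 9 of 19 genes of this list were higher, and 0, 0 and 2 lower.

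Set directly against each other, the library with PGN held higher levels than that with P. acnes for the mitochondrially encoded mRNAs, such as MT-ATP6 at 1140 against 3.05 FPKM (log2 ratio 8.14), MT-ND4 at 1929 against 9.03 FPKM (7.59) and MT-CO3 at 6068 against 32.7 FPKM (7.49). CLDN4 was at 3.72 against 221.5 FPKM (-5.56), CDC34, a ubiquitin-conjugating enzyme, at 24.1 against 316.1 FPKM (-3.66), the tetraspanin CD151 at 59.5 against 699.6 FPKM (-3.53) and TMEM222 at 6.38 against 94.2 FPKM (-3.69). After the GC subtraction the ratios were 4.49 for MT-ATP6, 3.94 for MT-ND4, 3.84 for MT-CO3, -5.69 for CLDN4, -2.41 for CDC34, -2.65 for CD151 and -3.36 for TMEM222. Outside the central 95% of random lists lay 8 of 33 lists. NRF2 targets (11 of 13 higher, median 2.24) were at percentile 99.35, heat shock genes (median 2.08) at 99.37, cell cycle genes (1.56) at 98.8, housekeeping genes (1.70) at 98.6, the mitochondrially encoded mRNAs (6.53) and the ribosomal protein list (2.30) at 100, immediate early genes (-0.11, but between 0.043 and 0.47 under 4 other settings) at 1.98 and immune cell markers (-0.80) at 0.76. With GC matching as well these percentiles were 98.4, 98.5, 81.3, 75.2, 99.995, 84.2, 14.5 and 0.04, while the medians after the GC subtraction were 1.08 for NRF2 targets and -0.13 for heat shock genes. Of 12631 kept genes 5754 were at least 2-fold higher and 1546 lower with PGN (78.8% higher), and Spearman's rho of the log2 ratio with GC content was -0.71 across genes. The share of higher genes was 47.2% after the GC subtraction, 92.6% after centring, which adds 0.48 to each log2 ratio, and 94.5% after upper-quartile scaling.

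Both treated libraries were compared with the same LA library. Of 12031 genes kept in both comparisons, 415 were at least 2-fold higher in both and 961 lower in both, against 148.3 and 502.2 for independent lists of these sizes and 14.1 and 33.2 in simulated libraries that share LA and hold no difference. The counts were 304 and 305 after the GC subtraction, against 103.2 and 149.0 for independent lists, and with upper-quartile scaling 1047 and 463, which turns the balance. Centring gave 207 and 1096, which does not turn it. The correlation of the log2 ratios across genes was 0.54 (0.34 after the GC subtraction), against 0.48 to 0.55 in the simulated libraries. Their covariance was 0.77 (0.30 after the GC subtraction) and at most 0.035 in the simulated ones. With 1 LA library, part of the excess may come from that shared library.

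The cytosolic ribosomal protein genes followed GC content in both comparisons. Of 82 kept, 11 were at least 2-fold higher and 58 lower with P. acnes, and 1 was higher and 10 were lower with PGN; Spearman's rho with GC content across these genes was 0.82 and 0.54.

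**Figure D4:**
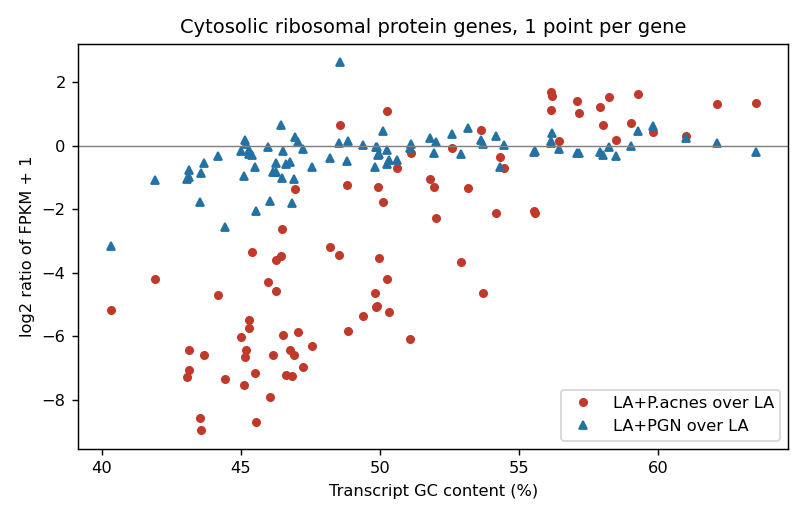
Log2 ratio of FPKM + 1 (vertical axis) against transcript GC content in percent (horizontal axis) for 82 cytosolic ribosomal protein genes, with 1 point per gene and comparison (circles LA with P. acnes over LA, triangles LA with PGN over LA). Genes of low GC content such as RPL7 (-8.57 with P. acnes, -1.77 with PGN) lie lowest.

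Some of the most extreme values belong to readthrough or overlapping gene models, between which the assembler can divide fragments, and are uncertain. With P. acnes these were AC011511.4 (24.96 against 0.060 FPKM), AC048338.1, AC010323.1 and CBSL, a near-copy of CBS, the last 3 listed at 0 in LA and at 19.4, 17.0 and 17.0 FPKM. On the low side were NME1-NME2 (4.39 against 1029 FPKM) and AC120057.3, listed at 0 against 225.3 FPKM. With PGN they were AP002990.1 (124.2 against 3.28 FPKM), AL662899.3 (19.2 against 0.095 FPKM), INO80B-WBP1 at 17.7 FPKM, TOMM6 (12.6 against 259.5 FPKM), TEN1 (1.02 against 31.1 FPKM) and TMEM189-UBE2V1, listed at 0 against 44.3 FPKM. URGCP-MRPS24 was listed at 0 with PGN and at 14.97 FPKM with P. acnes. FKBP1A, RPL36A, LAD1, AHR, MT-ATP6, MT-CO3 and MT-ND4 also overlap a coding gene on their strand. Whether a value of 0 is absence was not tested: 35 of 3826 coding genes at 10 FPKM or more in both other libraries were listed at 0 with P. acnes, against 1 of 2752 in LA and 0 of 2520 with PGN.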

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

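In this part the tests of GC content, of other cell types and of the mitochondrial mRNAs were chosen after the results were seen; those of depth and of the correlation were written before. For the mitochondrial mRNAs the decision to read 2 matched sets together also came after their values were known: the nuclear set alone had been read as favouring GC content. The count of markers of other cell types had been read as excluding such cells before the list percentiles were weighed with it.

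Against LA, 24 genes were at least 2-fold higher with P. acnes and at least 2-fold lower with PGN, and 102 were the other way round; after the GC adjustment these counts were 49 and 30. The difference between the treatments was not tested, since each has 1 library. Among the 24, TEN1 was at 31.1 FPKM in LA, 85.8 with P. acnes and 1.02 with PGN. Among the 102 were the proteasome subunit PSMA5 (43.1, 0.72 and 96.6 FPKM), DNAJC8 (6.69, 1.30 and 87.4 FPKM) and B2M, the light chain of class I histocompatibility molecules (81.5, 4.44 and 165.2 FPKM). After the GC adjustment the log2 ratios with P. acnes were 0.51 for TEN1 and -0.16 for PSMA5, short of the 2-fold rule, and 0.64 for DNAJC8 and 0.60 for B2M, so the last 2 no longer lay on opposite sides of LA. The coding genes of the smaller set (22) had a median GC content of 62.3% and those of the larger (82) of 47.8%.

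The excess of lower genes with P. acnes followed GC content: 74.2% of kept coding genes in the GC-poorest of 4 equal groups were at least 2-fold lower and 4.60% in the GC-richest, a ratio of 16.1. Thinning LA to the depth of the P. acnes library gave 0.93% of the observed number of lower genes, which argues against depth. Cells of another type as the source of the whole excess are argued against by the 82 kept cytosolic ribosomal protein genes. Apart from paralogues such as RPL39L and RPL22L1, every cell type expresses these genes. The median log2 ratio of the 82 was -3.58 (95% bootstrap interval over genes, not samples, -4.84 to -2.09). For the 30 ribosomal protein genes listed beforehand it was -2.12, at percentile 52.4 with GC matching. Spearman's rho of the log2 ratio with GC content over the 82 was 0.82. A fall that follows GC content this closely does not limit how large an admixture was. Admixture beside another cause stays open, since no table gives the level it would bring. Over 4 lists of markers of cells of another type 2 genes (CD68 and FBLN1) were at 10 FPKM or more and 2-fold above LA. THY1 was at 1.77 against 0.18 and COL1A1 at 6.77 against 3.35 FPKM. After the GC adjustment 5 of 6 kept immune markers were at least 2-fold higher, with a median of 2.16. Before it their list was at percentile 97.0 of GC-matched lists, and for PGN over P. acnes at 0.04, or 0.76 without GC matching. An under-representation of GC-poor transcripts in that library is a candidate explanation of the excess, and a response of the cells that happens to follow GC content stays open and was not tested, because library and treatment coincide.

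The 13 mitochondrially encoded mRNAs had a median log2 ratio of -6.71 with P. acnes. Against 57 abundant nuclear genes of the same GC range, all of them at least 2-fold lower and 32 of them ribosomal protein genes, this median was at percentile 4.78, inside the central 95%, and -0.68 from the nuclear median of -6.03. Against random lists matched on GC content and expression in wider classes it was at percentile 0.08. After the GC adjustment all 13 were still at least 2-fold lower, with a median of -2.44, but so were 41 of the 57 nuclear genes, with a median of -1.84 (-1.39 for the 25 that are not ribosomal protein genes). GC content and a selective loss of mitochondrial RNA cannot be told apart, since the sets differ in how closely they match the abundance of the mitochondrial mRNAs and the adjustment leaves abundant nuclear genes low as well.

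The log2 ratios of both treatments over LA were correlated across genes. Their covariance was 21.9 times the highest of 100 simulated sets that share LA, which argues against counting noise of that library as the cause. After the GC adjustment 38.6% of the covariance was left, between the bounds set beforehand for a common GC trend, so a common GC trend and a shared response cannot be told apart. Other irregularities of the LA library, such as its preparation, were not tested.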

How the results depend on the processing

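The GC adjustment, the GC-matched random lists and the removal of mitochondrially encoded genes were chosen after the results were seen; the other settings were fixed before. Over all settings, 2436 values of single genes and 687 list medians moved by less than 1.5-fold, 639 and 183 moved further in the same direction or without having passed a rule, and 23 and 6 that had passed the 2-fold rule or lain outside the central 95% of random lists changed sign. Where no construction is named, the cause was not tested.

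A pseudocount of 0.1 gave 1836 genes higher with PGN over LA and 683 higher in both treatments. A pseudocount of 5, which shrinks low genes, gave 1432 higher and 2781 lower with P. acnes over LA, 338 and 473 with PGN over LA, 2514 and 973 for PGN over P. acnes, and 145 higher and 422 lower in both. With no filter the correlation of both treatments was 0.50, the p53 target median with P. acnes was -0.19 and the immediate early gene median for PGN over P. acnes was 0.043. A minimum of 5 FPKM, which keeps fewer genes, gave 3318 lower with P. acnes, 665 higher with PGN, 3178 higher for PGN over P. acnes, a correlation of 0.57 and an immediate early median of 0.061. Centring gave 636 higher with P. acnes, 584 lower for PGN over P. acnes, 207 higher in both and an immediate early median of 0.37. Upper-quartile scaling gave 3588 higher and 502 lower with PGN, 458 lower for PGN over P. acnes, 1047 higher and 463 lower in both, a correlation of 0.51 and an immediate early median of 0.47.

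A 1.5-fold rule gave 2638 higher and 2198 lower with PGN, 2582 lower for PGN over P. acnes, and 1090 higher and 1947 lower in both. A 4-fold rule gave 305 higher and 2783 lower with P. acnes, 155 and 205 with PGN, 2426 and 153 for PGN over P. acnes, and 49 and 179 in both.

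After the GC adjustment 1955 genes were lower with P. acnes, 1776 were higher for PGN over P. acnes and 305 were lower in both, the correlation was 0.34, and 7 lists with P. acnes and 4 for PGN over P. acnes lay outside the central 95% of random lists, against 4 and 8 without it. With GC-matched random lists 2 did with P. acnes. Whether or not they lay outside that range, 8 of 33 list medians with P. acnes over LA, 4 of 32 with PGN over LA and 17 of 33 for PGN over P. acnes had the opposite sign. Sign changes of genes past the 2-fold rule were followed only in genes that the naming rule selected or that were chosen afterwards, not in all genes. Among those, signs changed with P. acnes over LA for AREG (1.68), ASNS (0.69), B2M (0.60), DNAJC8 (0.64), ELOVL5 (0.074), FABP5 (0.10), GAL (-0.30), HADHA (0.34), HSP90AA1 (0.030), HSPE1 (0.33), IDI1 (0.061), IL6 (1.07), LAMA3 (0.22), LDHA (0.80), MALAT1 (0.43), NQO1 (1.36), PGK1 (0.011), SNHG7 (-0.17), SNHG8 (2.57), SNHG16 (0.29) and SOD2 (0.60). For PGN over P. acnes they changed for AHR (-0.10), NQO1 (-1.39) and, of the medians outside the central 95%, that of heat shock (-0.13). Removing the mitochondrially encoded genes kept every count of genes within 1.5-fold. Depth limits genes near 1 FPKM and below, CYP1A1, CYP1B1, TIPARP and AHR among them.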

Other observations

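The genes and tests of this part were all chosen after the values were seen. Among small structured RNAs, 4 with higher values in both treated libraries were picked. RN7SK, which restrains transcription elongation, was at 140.2 FPKM in LA, 354.1 with P. acnes and 1412 with PGN. RMRP was at 126.3, 523.0 and 318.7 FPKM, RPPH1, the RNA of ribonuclease P, at 98.2, 465.4 and 283.1 FPKM, and RN7SL1, the RNA of the signal recognition particle, at 564.2, 2159 and 1182 FPKM. Their GC content was between 58.2% (RN7SK) and 64.6% (RPPH1). After the GC adjustment all 4 log2 ratios with P. acnes were short of the 2-fold rule, at 0.69 for RN7SK, 0.63 for RMRP, 0.73 for RPPH1 and 0.52 for RN7SL1. Others went differently, with BCYRN1 at 83.5, 0.72 and 44.9 FPKM and the sum of all snoRNAs at 310.1, 256.8 and 342.8 FPKM. The long non-coding RNA MALAT1, of 39.6% GC, was at 49.9, 1.99 and 96.7 FPKM, and the snoRNA host genes ZFAS1 and SNHG8 were at 560.1, 4.44 and 160.2 FPKM and at 207.4, 69.9 and 44.8 FPKM. Not all such host genes were lower in both treated libraries, as SNHG7 at 97.2, 201.5 and 86.3 FPKM and SNHG16 at 31.6, 1.29 and 106.8 FPKM show. After the GC adjustment the log2 ratios with P. acnes changed sign for MALAT1 (0.43), SNHG8 (2.57), SNHG16 (0.29) and SNHG7 (-0.17), so SNHG7 was then below LA in both treated libraries.

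At some loci with extreme values, overlapping gene models or near-copies were compared. With PGN, TOMM6 was at 12.6 against 259.5 FPKM in LA while AL365205.1, which overlaps it, was at 31.0 against 2.17 FPKM. AP002990.1 was at 124.2 against 3.28 FPKM beside EEF1G at 1391 against 1040 FPKM. With P. acnes NME1 was at 18.1 against 554.8 FPKM and NME2 at 1077 against 421.4 FPKM, and CBS was at 13.6 against 12.3 FPKM where its near-copy CBSL was listed at 0 in LA. Among coding genes at least 4-fold higher with PGN 18.8% overlapped another coding gene on their strand, against 11.3% of those within 2-fold; with P. acnes these shares were 21.2% and 11.8%. On the low side, 13.7% of those at least 4-fold lower with PGN and 11.3% with P. acnes did, the latter below the share within 2-fold.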
